A study of Homo sapiens with 7 samples.

How the data were processed

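N6-methyladenosine (m6A), the most common internal modification of mRNA, was mapped in HEK-293T cells, a human embryonic kidney line, by an antibody method and by a chemical method. In MeRIP-seq, fragmented RNA was captured with an antibody against m6A. In m6A-ORL, per the labels' protocols, fragments were treated in turn with NO/O2, with TDO and with a biotin-carrying probe called BA, captured on streptavidin beads and released with DTT. The labels list 7 samples, of which 4 are captured (IP) libraries with a peak list, 2 per method. The other 3 samples are inputs and were not analysed here.

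Per the labels, the RNA of m6A-ORL replicate 1 was total RNA and that of every other captured library was polyA RNA, although the shared protocol text describes oligo(dT) selection for all samples. RNA type and replicate therefore cannot be separated within m6A-ORL. No label says whether replicates came from separate cultures, so the p-values of method means measure only the spread between these libraries, which may be technical.

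Per the file headers, each deposited list has 12 BED columns, with the position, strand, blocks (pieces of a peak on either side of a splice junction), an Ensembl gene ID as the name and a score. The deposited score behaves as a p-value or q-value, since it lies between 0 and 0.0081 and was 0 for 287, 308, 70 and 2 peaks of MeRIP replicates 1 and 2 and m6A-ORL replicates 1 and 2, which is read as underflow. Which of these it is, the peak caller, its input library and its threshold are not given in the sources used here. Trim Galore, STAR, HOMER and the genome build hg38 are named, per the submitters' processing notes, without role or version. Each list belongs to 1 library, and it is not stated whether peaks were called per library. The authors' score was used only to rank or filter peaks within a list.

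Exact duplicate lines were removed, 4, 3, 2 and 1 in the same order of libraries. Read depth is unknown, so the number of peaks limits the precision, and intervals are exact (Clopper-Pearson) 95% binomial intervals of shares of peaks, which cover counting error only. A share of 0 is given with the limit that 3 peaks of the total would set.

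The files hold Ensembl IDs, and the RefSeq gene table used here (GRCh38.p14, the same build) carries none, so 0 IDs matched by ID. Names were assigned by position. An ID took the name of a RefSeq gene when at least 90% of the bases of its peaks lay in the span of exactly 1 gene, conflicts being settled by a 3-fold excess of covered bases and then by elimination. This named 9956 of 13566 IDs (73.4%), 9163 of them within 1 span and 793 by elimination, while 2494 stayed ambiguous and 1116 lay in no span. The table gives no strand and no exons, and a name can be wrong where genes overlap.

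Peaks of different lists were called shared when their blocks overlapped by at least 1 nt on the same strand. Placement of peaks in the exons of their gene, the background planned before the data were examined, needs exon annotation and was not run. A first substitute, random placement within the peak intervals of all 4 lists, left 95.0% ± 0.127 (SD of 100 placements) of MeRIP replicate 1 peaks on replicate 2 peaks against 87.3% observed, so it was saturated. It was replaced, after these values were seen, by 100 random shifts of each peak by 300 to 2000 nt. Shifted peaks can land in introns, so this background lies below chance within exons.

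A gene was assigned to a method when it had a peak in both of the method's libraries. The 15 gene lists were fixed at the same time. The share of a list's genes with peaks was compared with 10000 random lists matched on genomic gene span in 20 bins, drawn from the named genes with a peak in any library (protein-coding genes, or all genes for the lists that hold noncoding RNAs). The p-values are two-sided permutation p-values, adjusted by Benjamini-Hochberg over lists and methods, and the smallest unadjusted value they can give is 0.0002. The planned exact McNemar test compared the methods within each list. A test of the difference between methods against the difference in the matched random lists was added after the data were seen, because MeRIP has more genes overall. It works in percentage points, so a list whose MeRIP share is near its maximum has little room to differ toward MeRIP. These p-values measure the spread between draws of genes and describe 4 libraries, since genes are not replicates. The pattern meant for mitochondrial gene symbols matched none, so the genes of the mitochondrial chromosome were used. Matching on spliced length was planned, and genomic span replaced it.

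Method means over 2 libraries were compared by exact permutation of the method label over 3 splits, two-sided, for which the smallest p is 0.33. Position along a gene was measured on its genomic span, with windows of 300 nt at the 5' end and 1000 nt at the 3' end chosen after the lists were seen. A small structured RNA position is a small RNA gene of at most 400 nt that covers at least 50% of a peak on either strand, a rule also set after the lists were seen. Location in UTRs and coding sequence, distance to the stop codon, and the DRACH motif were planned and not run, since no genome sequence or exon annotation was used here.

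Named genes followed a rule fixed beforehand. It takes the 10 genes with the highest mean within-library percentile of their best score among genes with peaks in all 4 lists, the same number with peaks in both MeRIP lists and no m6A-ORL peak within their span, the same number with the methods exchanged, and any member of the fixed lists. Some genes that meet this rule are not reported here. Alternatives were stricter or equal-sized lists (7661 peaks), other overlap rules, peaks of 200 nt, protein-coding genes only, other backgrounds and leaving out each library. The background of all protein-coding genes also holds genes with no named peak, which may not be expressed. A list of expressed genes can therefore lie above it for that reason alone. Analyses ran in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. On simulated data with 8372 genes, 20 of 20 lists of 40 genes moved by 30 percentage points in opposite ways by method were recovered, none of 200 unchanged lists passed the adjusted threshold (13 had an unadjusted permutation p under 0.05), and an overlap of 59.7% was returned as 59.7%. Simulated peaks were drawn independently by method, and genes left without a simulated peak were kept. The simulation thus checks the calculation, not the effect of drawing lists from genes with a peak.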

Results

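Peaks of m6A were listed for 4 captured RNA libraries of HEK-293T cells, 2 made with an anti-m6A antibody (MeRIP) and 2 by chemical labelling and streptavidin capture (m6A-ORL). The series compares how the antibody and the chemical method perform. The MeRIP lists held 20760 and 20216 peaks in 9791 and 9638 genes. The m6A-ORL lists held 11022 peaks in 7203 genes for replicate 1 (labelled total RNA) and 7661 peaks in 4495 genes for replicate 2 (labelled polyA RNA). Means were 20488 ± 385 peaks for MeRIP and 9342 ± 2377 for m6A-ORL (SD, n = 2 each; exact two-sided permutation p = 0.33, the smallest that 3 splits allow). Median peak width was 211 nt in both MeRIP lists and 145.5 ± 4.95 nt (SD, n = 2) in the m6A-ORL lists.

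The first question was which transcripts carried peaks by both methods. Peaks were found in both libraries of both methods for 2138 genes, which is 81.7% of the 2617 genes of m6A-ORL and 23.9% of the 8939 genes of MeRIP. Independent lists of these sizes among the 13566 genes with any peak would share 1724. Leaving out m6A-ORL replicate 1 or 2, so that the method rests on 1 library, gave 3242 and 4425 shared genes. The best-scored shared genes were ACTB, the cytoplasmic beta-actin gene, with NCL (nucleolin) and EEF2, a translation elongation factor. They were followed by IRS4, an insulin receptor substrate, SRRM2, a component of nuclear speckles, and JUN, a subunit of the AP-1 transcription factor. SLC7A5, an amino acid transporter, the transcription factor SOX4 and the RNA-binding protein gene PCBP1 were also in this group.

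ACTB (ENSG00000075624; hg38 chromosome 7, 5527148 to 5530601, minus strand) had 3 peaks in each MeRIP list, 3 in m6A-ORL replicate 1 and 5 in replicate 2. SRRM2 (chromosome 16, 2752638 to 2771412) had 10 and 8 MeRIP peaks and 12 and 13 m6A-ORL peaks. EEF2 (chromosome 19, 3976056 to 3985463) had 3 MeRIP peaks in each list and 1 and 5 by m6A-ORL. IRS4 (chromosome X, 108719946 to 108736563) had 2 in each MeRIP list, and 5 and 6. For SOX4 (chromosome 6, 21593751 to 21598619) the lists gave 1 and 1 against 7 and 3. JUN (chromosome 1, 58780791 to 58784047) had 2 and 2 against 5 and 3.

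**Figure D1:**
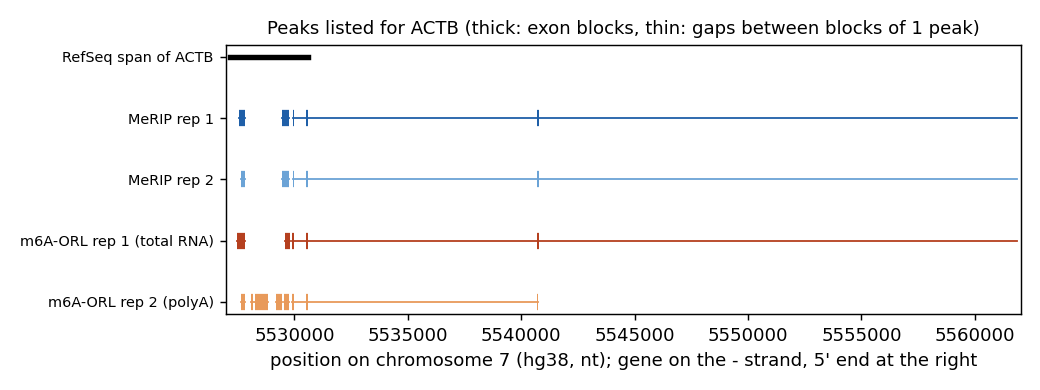
Peaks listed for ACTB in the 4 libraries along hg38 chromosome 7 (position in nt), with the RefSeq gene span in black; thick bars are peak blocks and thin lines are the gaps within 1 peak. The gene reads from right to left, and all 4 libraries have peaks near its 3' end, with 3 peaks in each MeRIP list and in m6A-ORL replicate 1 and 5 in replicate 2.

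Peaks in both MeRIP libraries and in neither m6A-ORL library were listed for 3410 genes. Among those with a name and no m6A-ORL peak anywhere in their span (2236 genes), the best-scored were C21orf58, ABHD17A, a depalmitoylating enzyme, P3H3, a relative of collagen prolyl hydroxylases, SAMD11, and the ubiquitin ligase gene RNF25. HS6ST1, a heparan sulfate sulfotransferase, R3HCC1, ZNHIT2, PGGHG, a glucosidase acting on collagen, and TMEM121 followed. C21orf58 (chromosome 21, 46300430 to 46323870) had 7 and 6 MeRIP peaks, ABHD17A (chromosome 19, 1876810 to 1885496) had 6 in each list, and PGGHG (chromosome 11, 289126 to 296107) had 5 and 7.

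Peaks in both m6A-ORL libraries and in neither MeRIP library were listed for 364 genes. Of the 239 with a name and no MeRIP peak in their span, 8 of the 10 best-scored lay on the mitochondrial chromosome. These were the mitochondrial ribosomal RNA genes RNR1 and RNR2, the complex I subunits ND1, ND2 and ND4, COX1, ATP6 and CYTB. The remaining pair were RPS4X, a ribosomal protein gene (chromosome X, 72272042 to 72277248; 1 and 3 peaks), and ACTG1, the cytoplasmic gamma-actin gene (chromosome 17, 81509971 to 81512799; 3 and 4 peaks). ACTG1 and RPS4X have close paralogs or pseudogene copies (ACTB in the case of ACTG1), and how reads that map to several places were treated is not given in the sources used here. Among named genes the median genomic span was 12682 nt for the m6A-ORL-only group, 22560 nt for the MeRIP-only group and 28393 nt for the shared group.

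Several gene groups fixed beforehand differed between the methods. Of 49 genes for cytosolic ribosomal proteins with a named peak in any list (83 list members), 12 (24.5%) had peaks by MeRIP and 26 (53.1%) by m6A-ORL. Span-matched random lists averaged 75.3% and 28.9%, so the group lay below them by MeRIP (adjusted permutation p = 0.0008) and above them by m6A-ORL (adjusted permutation p = 0.0025). Within the group 19 genes had peaks in both m6A-ORL lists but not both MeRIP lists, and 5 had the reverse (exact McNemar adjusted p = 0.018). Each of the 5 had a peak in 1 m6A-ORL list. RPS3 and RPL38 had 2 and 1, and 2 and 2, m6A-ORL peaks and no MeRIP peak, whereas RPL37 had 3 peaks in each MeRIP list and 0 and 1 by m6A-ORL. Most of these genes have processed pseudogenes, with which reads can be shared.

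Nuclear genes of the respiratory chain and ATP synthase also had a low MeRIP share, 13 of 44 (29.5% against 74.7% in matched lists, adjusted permutation p = 0.0008). Their m6A-ORL share, 16 of 44 (36.4% against 26.7%), did not pass the test against these lists (adjusted permutation p = 0.25), and it passed with all protein-coding genes as background (19.3% against 9.98%, adjusted permutation p = 0.02). The wider background includes genes without a named peak, so this pass can reflect expression. ATP5F1B and NDUFB7 each had 1 peak in both m6A-ORL lists and none by MeRIP. The 9 genes with peaks in both MeRIP lists but not both m6A-ORL lists, and the 12 with the reverse, did not differ in number (exact McNemar adjusted p = 0.71). Measured against the difference in matched lists, m6A-ORL exceeded MeRIP by 74.95 percentage points for ribosomal proteins and by 54.8 for the respiratory chain (adjusted permutation p = 0.00056 for each). These were 57.4 and 33.8 points at equal list length, and 33.2 and 22.2 points with all protein-coding genes as the background.

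Replication histone genes, whose mRNAs mostly end without a poly(A) tail, had peaks by MeRIP in 2 of 21 (adjusted permutation p = 0.0008) and by m6A-ORL in 4 of 21 (adjusted permutation p = 0.59). The m6A-ORL minus MeRIP difference was 53.1 points above matched lists (adjusted permutation p = 0.00056), 93.6 without m6A-ORL replicate 2 and 31.3 at equal list length (adjusted permutation p = 0.049). The 53.1 points reflect the low MeRIP share, since the m6A-ORL share was not above matched lists. With all protein-coding genes as background the difference was 8.24 points (adjusted permutation p = 0.013), and the MeRIP share no longer passed (2.70% against 9.05%, adjusted permutation p = 0.062). The total RNA library had a peak in 17 of the 21 and the polyA m6A-ORL library in 8. No gene of the mitochondrial chromosome had a MeRIP peak. Of its 13 protein-coding genes, 8 had peaks in both m6A-ORL libraries (61.5% against 26.6% in matched lists, adjusted permutation p = 0.037; exact McNemar adjusted p = 0.018).

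ZNF genes, which are named for zinc finger proteins, went the other way. By MeRIP 240 of 277 (86.6%) had peaks, above the 75.8% of matched lists, and by m6A-ORL 47 (17.0%), below 25.3% (adjusted permutation p = 0.0008 and 0.0021). With all protein-coding genes as background the MeRIP share still passed, and the m6A-ORL share of ZNF genes did not (9.85% against 10.8%, adjusted permutation p = 0.55). ZNF618 had 9 and 8 MeRIP peaks against 5 and 0, ZNF318 9 and 8 against 7 and 0, and ZNF517 7 and 5 against none. For 195 ZNF genes peaks were in both MeRIP lists but not in both m6A-ORL lists, and for 2 the reverse (exact McNemar adjusted p = 2.7e-54). Many of the 195 had a peak in 1 m6A-ORL list, as 163 of the 277 genes had one in replicate 1. Relative to matched lists the difference was -19.2 percentage points (adjusted permutation p = 0.00056). It was -30.2 points without m6A-ORL replicate 1, and it did not pass the test without m6A-ORL replicate 2 (-5.56 points, adjusted permutation p = 0.28) or with lists of equal length (-5.74 points, adjusted permutation p = 0.14).

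Writers, erasers and readers of m6A carried peaks themselves. Of the 24 list members, all 20 with a named peak in any list had them by MeRIP (75.3% in matched lists, adjusted permutation p = 0.018), and 9 by m6A-ORL (24.1% in matched lists, adjusted permutation p = 0.11). The remaining members may have peaks under IDs that got no name. With all protein-coding genes as background the m6A-ORL share of these genes passed (37.5% against 11.1%, adjusted permutation p = 0.002). For 11 of them peaks were in both MeRIP lists but not in both m6A-ORL lists, and for 0 the reverse (exact McNemar adjusted p = 0.0034). Most of the 11, such as VIRMA and YTHDF3 (3 and 0 m6A-ORL peaks each), had a peak in 1 m6A-ORL list. Against the difference in matched lists the value was -3.78 points and did not pass (adjusted permutation p = 0.92). With all 20 genes listed by MeRIP, its share had no room to rise, so this test says little about a preference for MeRIP. METTL3, the catalytic subunit of the methyltransferase, had 1 peak in each MeRIP list and none by m6A-ORL, while the reader YTHDF2 had 3 and 3, and 3 and 2, and the demethylase ALKBH5 1 and 3, and 1 and 3. Transcripts often used as m6A examples had peaks in 13 of 14 cases by MeRIP (adjusted permutation p = 0.2, and 0.00043 for the protein-coding ones with all protein-coding genes as background) and 11 of 14 by m6A-ORL (78.6% against 23.2% in matched lists, adjusted permutation p = 0.0008). MYC had 3 peaks in each MeRIP list and 4 and 2 by m6A-ORL, and the long noncoding RNA MALAT1 had 2 and 2, and 3 and 3. HSPA1A had 3 in each MeRIP list and none by m6A-ORL. The ID placed by position at TPT1 (ENSG00000273149) had none by MeRIP and 1 and 2 by m6A-ORL, and its peaks may belong to another gene in that span.

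Chromatin regulators had peaks by m6A-ORL in 25 of 37 (67.6% against 23.1% in matched lists, adjusted permutation p = 0.0008) and by MeRIP in 32 of 37 (86.5% against 75.5%, adjusted permutation p = 0.22). The histone methyltransferase gene KMT2D carried 17 and 14 MeRIP peaks and 12 in each m6A-ORL list, and SETD1A 6 and 5, and 5 and 9. The difference between methods (33.5 points, adjusted permutation p = 0.0019) did not pass the test at equal list length (2.0 points), without m6A-ORL replicate 2 (13.8 points), when 1 library per method sufficed (17.9 points) or with all protein-coding genes as background (8.12 points). Immediate early and short-lived transcription factors had peaks in 12 of 22 by m6A-ORL (54.5% against 28.6%, adjusted permutation p = 0.035) and 19 of 22 by MeRIP (adjusted permutation p = 0.35). The methods did not differ in this group by the test against matched lists (14.2 points, adjusted permutation p = 0.43, and -13.6 points at equal list length). Wnt, Notch and Hippo genes (33 of 36 by MeRIP, 12 by m6A-ORL), HOX genes (21 and 9 of 24), DNA repair and cell cycle genes (17 and 11 of 25) and selected long noncoding RNAs (7 and 5 of 13) did not pass the permutation test by either method, with adjusted p from 0.066 to 0.52. More Wnt, Notch and Hippo genes had peaks in both MeRIP lists but not both m6A-ORL lists than the reverse (21 against 0, exact McNemar adjusted p = 6.6e-06). The same held for HOX genes (12 against 0, exact McNemar adjusted p = 0.0023). Genes counted here can have a peak in 1 m6A-ORL list, and the McNemar test does not allow for the larger MeRIP lists. The permutation result holds only among genes with a peak in some library. With all protein-coding genes as background, Wnt, Notch and Hippo genes (adjusted permutation p = 0.00043 and 0.0041) and HOX genes (0.00043 and 0.023) lay above matched lists by MeRIP and by m6A-ORL, and DNA repair and cell cycle genes by m6A-ORL (0.012). The Wnt, Notch and Hippo difference was then -27.8 points (adjusted permutation p = 0.001). Chromatin regulators and immediate early genes then lay above matched lists by MeRIP too (0.00043 each). Markers of other cell types, such as ALB, HBB and PTPRC, had no named peak in any library. By MeRIP they lay below the background of all protein-coding genes (0% against 26.5%, adjusted permutation p = 0.033). That background holds genes without a named peak, so passing it can reflect expression, which was not measured.

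**Figure D2:**
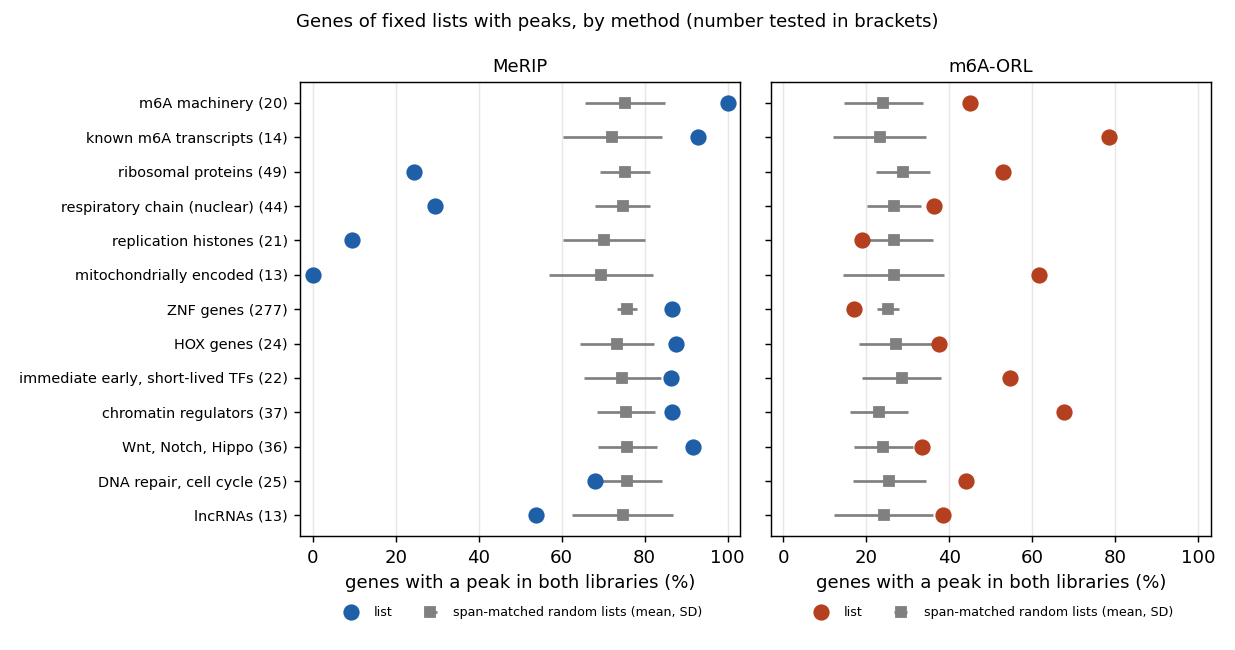
Percent of the genes of each fixed list with a peak in both libraries of MeRIP (left) or m6A-ORL (right), with the number of genes tested in brackets; coloured points are the lists, and grey squares with bars are the mean and SD of 10000 span-matched random lists. Ribosomal protein genes stand at 24.5% by MeRIP, below their matched lists, and at 53.1% by m6A-ORL, above them.

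The next question was whether the methods placed peaks at the same positions. The MeRIP libraries shared most of theirs, with 83.6% of replicate 1 peaks overlapped in replicate 2 (95% interval 83.0 to 84.1) and 86.0% the other way. Of m6A-ORL peaks, 13.8% of replicate 1 (13.2 to 14.5) and 19.6% of replicate 2 (18.7 to 20.5) were overlapped by the other m6A-ORL library, which was made from another type of RNA. The labels list a single MeRIP input and an input for each m6A-ORL library, and which input each list used is not given. MeRIP overlapped 48.4% ± 4.14 of m6A-ORL peaks (SD over 4 directed pairs of libraries), ranging from 44.1% to 52.9%, and m6A-ORL overlapped 19.9% ± 6.03 of MeRIP peaks. At equal list length these means were 36.9% and 31.6%. The mean within-method overlap exceeded the between-method overlap by 16.6 points, and no split of 4 libraries can give an exact permutation p under 0.33.

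Within genes that had peaks in both lists compared, 71.0% of m6A-ORL replicate 1 peaks and 56.4% of replicate 2 peaks were overlapped by MeRIP replicate 1. After random shifts of 300 to 2000 nt these were 17.4% ± 0.342 and 16.6% ± 0.375 (SD of 100 shifts). Between the m6A-ORL libraries the share in common genes was 31.2%, against 7.16% ± 0.321 after shifting. Over all genes and counting a peak in either MeRIP list, another measure than above, m6A-ORL peaks present in both m6A-ORL lists were overlapped in 75.1% (1143 of 1522) and 75.5% (1135 of 1504) of cases. The rest were overlapped in 51.4% and 41.0%.

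**Figure D3:**
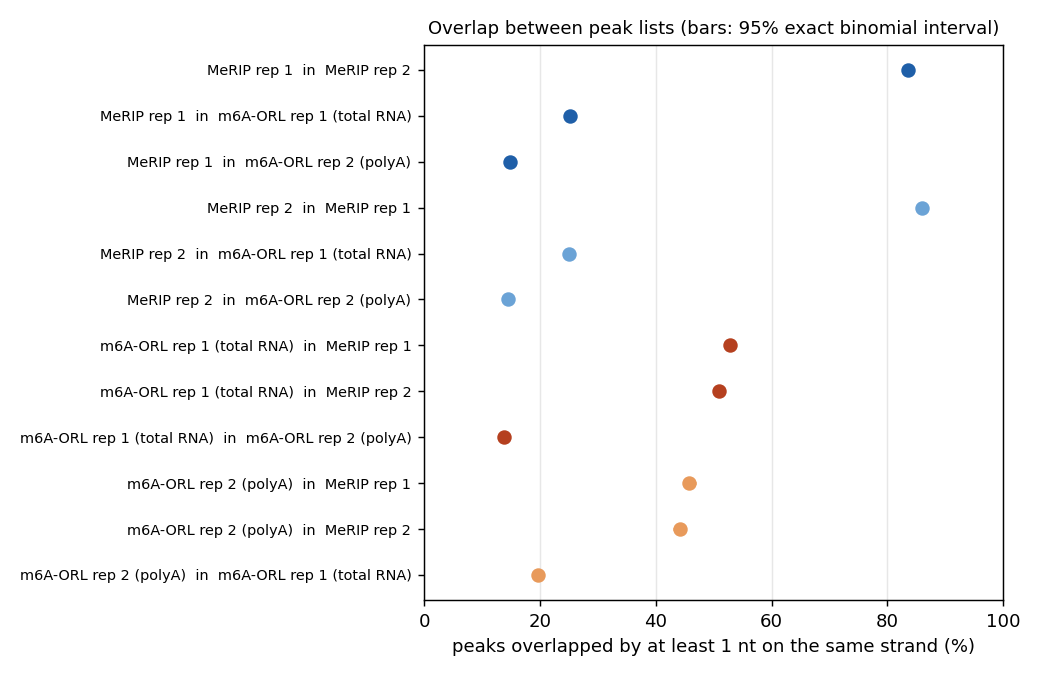
Percent of the peaks of 1 library overlapped by at least 1 nt on the same strand by peaks of another, for the 12 directed pairs of the 4 libraries; bars are exact 95% binomial intervals, mostly smaller than the points. The MeRIP pair stands at 83.6% and 86.0%, and the m6A-ORL pair at 13.8% and 19.6%.

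Along genes, peaks of both methods were most frequent at the 3' end of the genomic span. The first 10% of the span held 14.9% and 15.3% of MeRIP peaks, and 15.2% and 18.8% of m6A-ORL peaks. Without an exon background, these positions cannot be told apart from where exon sequence lies in a span. The final 10% of the genomic span held 36.4% and 36.3% of MeRIP peaks in named genes and 32.6% and 28.3% of m6A-ORL peaks, which are means of 36.4% ± 0.0632 and 30.5% ± 3.02 (SD, n = 2; exact permutation p = 0.33). Peaks within 300 nt of the 5' end made up 7.50% and 7.51% by MeRIP, and 16.1% and 10.5% by m6A-ORL. The difference was 5.76 points over all named genes, 3.16 in protein-coding genes, 2.96 without m6A-ORL replicate 1 and 0.348 in genes with peaks in all 4 lists. Peaks spanning a splice junction were 16.9% and 16.3% of the MeRIP lists, 9.88% of m6A-ORL replicate 1 and 27.8% of replicate 2, so the m6A-ORL libraries lay on opposite sides of MeRIP. Chromosome 19 held 8.85% and 8.67% of MeRIP peaks, and 6.15% and 13.7% of m6A-ORL peaks.

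**Figure D4:**
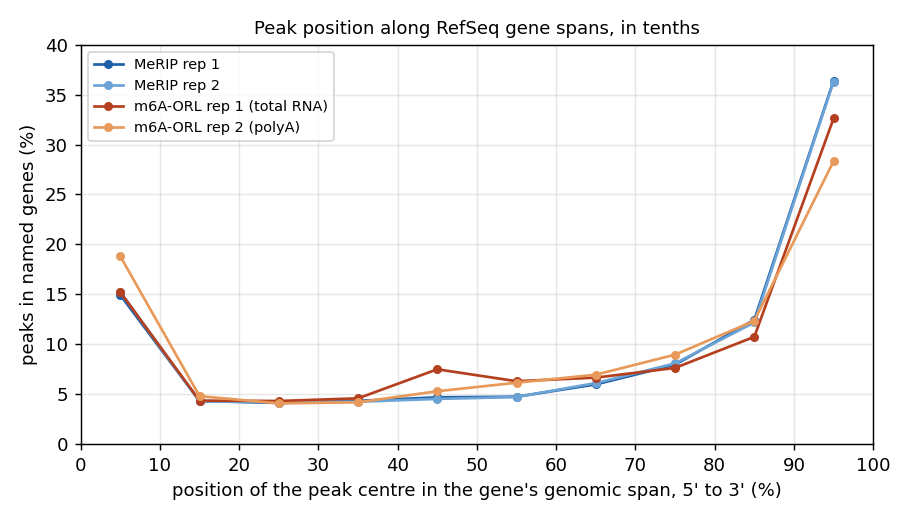
Share of peaks in named genes (%) by the position of the peak centre in the genomic span of its gene, from 5' to 3' in steps of 10%, 1 line per library. The last step is the highest in all 4 libraries, from 28.3% in m6A-ORL replicate 2 to 36.4% in MeRIP replicate 1.

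The m6A-ORL libraries differed in the RNA classes they held, which the labels pair with total RNA in replicate 1 and polyA RNA in replicate 2, with 1 library each and no test between RNA types. Small structured RNA positions took 884 peaks of the total RNA library (8.02%, 95% interval 7.52 to 8.54) and 15 of the polyA library (0.196%, 0.110 to 0.323), with 17 and 12 in the MeRIP lists. In the total RNA library 205 lay at copies of RNU6, a spliceosomal RNA, 203 at RNA5S (ribosomal RNA), 143 at RN7SL (signal recognition particle RNA), 80 at RN7SK, 71 at RNU1 and 43 at SNORD genes. Many of these copies are near-identical, so a single RNA can yield peaks at several. Pseudogenes took 7.79% of the named peaks of the total RNA library and 1.11% of the polyA library, against 1.98% and 2.04% by MeRIP. This class can hold some of the same peaks, since a small RNA copy annotated as a pseudogene counts in both.

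Mitochondrial peaks numbered 32 in the total RNA library (0.290%, 95% interval 0.199 to 0.410) and 23 in the polyA library (0.30%, 0.190 to 0.450). MeRIP listed 0 of 20760 and 0 of 20216, which allow shares of up to 0.0145% and 0.0148% of peaks. ND4 was touched by 3 peaks and CYTB by 2 in each m6A-ORL library, while the mitochondrial tRNA genes TRNF and TRNW had a peak in the total RNA library alone and TRNV had 1 in each. Long noncoding RNA genes took 5.10% and 5.37% of named MeRIP peaks, and 2.35% and 1.71% of named m6A-ORL peaks.

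Better-scored MeRIP peaks were more often found by m6A-ORL. In the best quintile of the deposited score 70.0% and 69.8% of MeRIP peaks were overlapped by an m6A-ORL peak, compared with 11.03% and 11.1% in the worst. Median widths in these quintiles were 570 and 91 nt, and with every peak set to 200 nt the shares were 56.8% and 56.3% against 12.3% in each. For m6A-ORL replicate 2 the share overlapped by MeRIP was 57.6% in the best and 39.1% in the worst quintile, with median widths of 241 and 61 nt, and 39.3% and 29.4% with every peak set to 200 nt. In replicate 1 it was 53.3% in the best, 65.0% in the second and 44.2% in the worst, and 43.5%, 53.4% and 37.8% at 200 nt.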

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

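The test of the difference between methods against matched lists, the respiratory chain test of pseudogenes and both tests on mitochondrial peaks were chosen only after the results they bear on had been seen. The other abundant mRNAs and the split by named pseudogenes were chosen after the ribosomal protein pattern had appeared and before their own values were computed. Random placement within peak intervals, the background of the test of scattered peaks, had been replaced elsewhere once it proved saturated, and its value is kept here.

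In 4 gene groups the methods lay on opposite sides of the matched lists and differed by permutation. Ribosomal protein genes had an m6A-ORL minus MeRIP difference of 74.95 percentage points above matched lists, respiratory chain genes 54.8, mitochondrially encoded genes 104 and ZNF genes -19.2 (each unadjusted permutation p = 0.0002, the smallest possible here). The m6A-ORL share of respiratory chain genes did not pass against matched genes with a peak (adjusted permutation p = 0.25) and passed with all protein-coding genes as background (adjusted permutation p = 0.02), and under that background the low m6A-ORL share of ZNF genes (adjusted permutation p = 0.55) and the MeRIP share of mitochondrial genes (adjusted permutation p = 0.73) did not pass. The ZNF difference was -5.56 points without m6A-ORL replicate 2, which did not pass the test. Because the matched lists hold only genes with a peak in some library, part of these sizes comes from that choice, and with all protein-coding genes as background the values were 33.2, 22.2, 65.9 and -18.4 points, all past the threshold.

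For ribosomal protein and respiratory chain genes, abundance was tested first. Other abundant mRNAs (30 genes such as glycolytic enzymes, tubulins and chaperones) showed a difference of 74.4 points (permutation p = 0.0002), so a tendency of m6A-ORL peaks, or of missing MeRIP peaks, to follow abundance is consistent with both groups, although expression itself was not measured here. Against reads shared with processed pseudogenes as the whole cause, the 21 list genes without a named pseudogene still differed by 38.3 points (permutation p = 0.0064). This came mostly from a low MeRIP share (47.6% against 74.4%). Their m6A-ORL share did not pass (38.1% against 26.5%, permutation p = 0.33), with 10 genes by MeRIP and 8 by m6A-ORL. In the 72 genes with a named pseudogene the m6A-ORL share passed (47.2% against 28.1%, permutation p = 0.0008). A gain of m6A-ORL peaks apart from pseudogenes is therefore not shown. Of the 21, 20 are respiratory chain genes, so pseudogenes stay open for ribosomal proteins, where 48 of 49 have one. The 54.8 points of the respiratory chain alone decide nothing because 24 of its 44 genes have one too. Whether the m6A-ORL peaks in these genes are scattered cannot be told apart from fixed positions: replicate 2 overlapped 29.6% of 54 replicate 1 peaks against 82.8% ± 3.85 (SD) for random placement, but that background is saturated, as it also lay above the MeRIP pair. A difference in true methylation between what the methods capture stays open and untested.

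Mitochondrial peaks were in both m6A-ORL lists and in neither MeRIP list. Total RNA in replicate 1 as the cause is contradicted by the 23 mitochondrial peaks of the polyA m6A-ORL library, beside 32 in the total RNA library. A filter that left the mitochondrial chromosome out of the MeRIP lists cannot be told apart from a lack of antibody peaks. Nuclear copies of mitochondrial genes held 26 peaks in m6A-ORL replicate 1, 7 in replicate 2 and 0 by MeRIP, which goes against a filter on finished lists, but how shared reads were placed is not given in the sources used here. No biological explanation was tested.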

How the results depend on the processing

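Equal length with 200 nt peaks, 200 nt peaks in the score comparison, genes with peaks in all 4 lists, 1 library sufficing in the gene lists, the background of all protein-coding genes and peaks of similar width for location were chosen after seeing the data. Stricter overlap rules lowered all 3 overlap values, and no value changed direction past its threshold. For the MeRIP pair (84.8%), overlap was 90.9% in the better-scored 50% of each list, 92.2% at equal length, 74.4% when at least 50% of both peaks had to overlap, 75.3% for centres within 100 nt, 85.6% in protein-coding genes, 81.2% with 200 nt peaks and 87.5% with equal length and 200 nt. For the m6A-ORL pair (16.7%) it was 6.88% with 50% of both peaks, 10.4% by centres and 15.5% with equal length and 200 nt. Between methods (34.2%) it was 10.0% with 50% of both peaks and 17.6% by centres. The excess of m6A-ORL peaks near the 5' end (5.76 points) was 10.1 in the better-scored 50%, 0.348 in genes with peaks in all 4 lists, 3.16 in protein-coding genes and 2.96 without m6A-ORL replicate 1. Genes by MeRIP (8939) numbered 5911 in the better-scored 50% and 4859 at equal length. Genes by m6A-ORL (2617) numbered 1129 in the better-scored 50%, 9081 when 1 library sufficed, and 2617 to 7203 when a library was left out, 4495 without m6A-ORL replicate 1 and 7203 without replicate 2. Genes by both methods (2138) numbered 847, 6005, and 2167 to 4425, with 3242 without m6A-ORL replicate 1 and 4425 without replicate 2, because a method then rests on 1 library. Lists off their matched expectation by m6A-ORL (6) became 10 with all protein-coding genes as background, and lists with a difference between methods (6) numbered 6 to 10 when a library was left out, 10 without MeRIP replicate 2, small structured RNAs included. The gain in sharing from the worst to the best quintile of MeRIP peaks (58.8 points) was 33.9 between the better and worse 50% and 44.2 with 200 nt peaks. The excess of small structured RNA peaks in m6A-ORL replicate 1 (7.82 points) was 9.35 at equal length. Apart from the overlap changes that follow from stricter rules by construction, the cause was not tested.

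In the other 90 settings of the main values the result stayed within its spread or within 1.5 times its count. Some of these could not change, since leaving out a library does not alter the pair overlap or gene count of the other method. Others stayed within a wide spread. In named genes, the m6A-ORL minus MeRIP difference in junction-spanning peaks (2.05 points) was -7.15 without m6A-ORL replicate 2 and 11.2 without replicate 1. Overlap between methods (34.2%) was 24.0% with equal length and 200 nt, against an SD over both directions of comparison. Such settings say little about stability. For differences of single gene lists, 93 of 110 settings kept their side of the threshold and direction where one was called, 6 no longer passed and 11 newly passed. Those that no longer passed were the ZNF and chromatin regulator lists. Those that newly passed were the m6A example, DNA repair, long noncoding RNA, Wnt and, in 4 settings, small structured RNA lists. For small structured RNAs (1 of 356 genes by MeRIP, 0 by m6A-ORL in both libraries; 352 in replicate 1 and 3 in replicate 2) span matching is void, because these genes fill their own length bins. No paired analysis was possible because peak lists give no fit with a replicate block and the results come from no model over libraries. Location in transcripts by UTR and coding sequence, with its alternatives, the motif analysis and any overlap with exons were not run for lack of a genome and exon annotation in this work. Depth is unknown, so an unlisted gene cannot be called unmethylated.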

Other observations

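The overlap of equal-sized, equal-width lists and of the best-scored peaks was chosen after the low m6A-ORL overlap had been seen, before those values were computed.

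Long noncoding RNAs of the fixed list differed gene by gene. TUG1 carried 11 and 12 MeRIP peaks, and 8 and 2 by m6A-ORL, NEAT1, the scaffold of paraspeckles, carried 6 and 6, and 2 and 2, and JPX 4 in each MeRIP list and none by m6A-ORL. SNHG1 and GAS5, which host small nucleolar RNAs in their introns, had 4 and 1 peaks in the total RNA m6A-ORL library and none in the other 3 libraries. Among HOX genes, HOXA10 had 4 and 2 MeRIP peaks and 1 and 2 by m6A-ORL, and HOXB13 had 3 in each MeRIP list and none by m6A-ORL. Among DNA repair genes, BRCA1 had 4 peaks in m6A-ORL replicate 1 alone, and BRCA2 had 3 and 2 by MeRIP and 5 and 0 by m6A-ORL.

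Other abundant mRNAs showed 22 of 30 genes with peaks by m6A-ORL (73.3% against 27.4% in matched lists) and 14 of 30 by MeRIP (46.7% against 75.05%; exact McNemar p = 0.057). The glycolytic genes ALDOA, LDHA and TPI1 had 2 and 3, 1 and 2, and 1 and 3 m6A-ORL peaks and none by MeRIP. P4HB, a protein disulfide isomerase, had 5 and 5, and 2 and 5, and the tubulin gene TUBB4B 4 and 4, and 2 and 5. The list shares ACTB, EEF2 and TPT1 with the list of m6A example transcripts.

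The m6A-ORL lists overlapped each other less than either was overlapped by MeRIP. RNA classes outside protein-coding genes do not account for it, since among protein-coding genes the m6A-ORL pair shared 16.9% and MeRIP overlapped 53.5%. Longer lists and wider peaks of MeRIP account for most of the gap between 16.7% and 48.4% but not for all, as with equal number and 200 nt peaks the values were 15.5% and 24.2%. Of the 1000 best m6A-ORL peaks, 33.8% were overlapped by the other m6A-ORL list and 46.3% by MeRIP, and for the 500 best the values were 33.5% and 37.0%. These compare with whole lists, so the longer lists and wider peaks of MeRIP enter again. Weak peaks as a cause therefore stay open. What also stays open is the RNA type, total against polyA, which is confounded with the replicate and was not tested, and differences in how each list was called.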
